A study of Mus musculus with 18 samples.

How the data were processed

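Gene expression was measured by RNA sequencing in mouse bone marrow-derived macrophages (BMDMs), the macrophages that grow out of bone marrow in medium with L929 cell supernatant, a source of the growth factor M-CSF. Per the labels, the cells came from C57BL/6J wild-type or TLR4-knockout mice and were treated on day 7 of differentiation for 24 h in serum-free IMDM. The treatments were water, GM (the disaccharide GlcNAc-MurNAc, a repeating unit of bacterial peptidoglycan) and MDP (muramyl dipeptide). The labels spell MDP as MurNAc-D-Ala-L-Gln, whereas the muramyl dipeptide known to activate NOD2 is MurNAc-L-Ala-D-isoGln, and the files do not settle which molecule was used. The doses are not stated. The 18 samples form 6 groups of 3 (2 genotypes by 3 treatments). The labels call the 3 samples of a group biological replicates without saying whether they were separate animals or cultures, so p-values measure the spread between these samples, which may be partly technical.

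Per the submitters' processing notes, reads from poly(A)-enriched directional libraries were aligned with HISAT2 2.0.5 to mouse build GRCm39 and counted per gene with featureCounts 1.5.0-p3. The settings, the use of strand and the annotation release are not stated, so reads shared between related genes may have been treated in more than 1 way. The deposited table that was used holds the authors' raw read counts for 56748 genes in all 18 samples, checked to be whole numbers. A deposited table in FPKM (fragments scaled to gene length and library size, computed by the authors) was used only for a check: it equalled the counts divided by the gene length and by an effective library size that differed from the total count by a factor of 0.8892 to 1.061 per library. Gene positions were taken from the count table (GRCm39). The annotation at hand was of another build (GRCm38) and its coordinates were not used. Poly(A) selection leaves out most histone and other unpolyadenylated transcripts.

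Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 15450 genes, holding at least 99.92% of the counts of every library, and libraries were scaled with TMM factors (0.877 to 1.057). A single quasi-likelihood fit of all 18 libraries with 1 mean per group (12 residual degrees of freedom, robust) gave 9 comparisons: GM against water, MDP against water and GM against MDP in each genotype, knockout against wild type in water, and the GM and MDP responses in wild type minus those in knockout. Tests were 2-sided F tests and genes passed at a Benjamini-Hochberg adjusted p below 0.05. Standard errors (SE) are those of the fitted log2 fold change, and levels are counts scaled to a fixed effective library size (CPM) on the TMM scale. These choices, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

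Whether the fit calls genes at the stated rate was tested on simulated data, in which 67, 67 and 66 of 15450 genes changed 1.5-, 2- and 4-fold. With the same spread in all groups, the fit of all 18 libraries recovered 38.8%, 73.1% and 98.5% of them for GM in wild type, and 5.41% of its calls were false. For GM in knockout it recovered 31.3%, 73.1% and 95.5% with 3.62% false calls, and for MDP in knockout 32.8%, 86.6% and 90.9% with 4.11%. The real groups did not share 1 spread: the biological coefficient of variation was 35.4% in wild-type water, 27.6% in wild-type GM, 8.09% in wild-type MDP and 5.71%, 6.12% and 6.5% in knockout water, GM and MDP. When each simulated group had its own spread, 81% of the 816 calls for GM in wild type were false, whereas for GM in knockout 0.806% of 124 calls were false and 25.4%, 61.2% and 98.5% of the changed genes were recovered. The fit of the 6 compared libraries then made 10.6% false calls for GM in wild type, recovering 0%, 17.9% and 71.2%. For GM in knockout it made 8.37% false calls and recovered 85.1%, 94% and 100%, and for MDP in knockout it made 5.91% and recovered 89.6%, 98.5% and 98.5%, where the fit of all 18 libraries had recovered 25.4%, 76.1% and 93.9%. A limma-voom fit with a spread for each group made 41.4% false calls for GM in wild type, 8.04% for GM in knockout and 6.37% for MDP in knockout. In these simulations the fit of all 18 libraries therefore over-called GM against water in wild type. For GM and MDP against water in knockout it recovered fewer changes than the fit of 6. The shares of false calls depend on how many changed genes were planted. Noise was drawn for each gene on its own, without a shift shared by a whole library, so these shares do not carry over to the real calls. The other comparisons were not simulated. Counts of the fit of all 18 libraries are given beside those of the fit of the compared libraries (6, or 12 for the differences between genotypes).

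Gene lists of 18 response programs and of cell type markers were tested with camera (limma 3.58.1, preset correlation 0.01) over lists with at least 5 tested members, which gave 27 lists. Calls were read again with an estimated correlation and with fry, whose p tests whether a list's genes move on balance 1 way and does not compare the list with other genes. The correlation was estimated over all 18 libraries, so in knockout comparisons it includes the spread of the wild-type groups. Of 243 list tests, 122 were called by camera, 37 of these with an estimated correlation as well, and 107 tests by fry. The median, the mean and the camera direction differed in sign in 31 tests, 1 of them called: the osteoclast list for MDP in wild type (median -0.33, mean 0.22). No erythroid gene of the 9 listed was tested (0 of 9 passed the filter).

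Genes were named by rule: up to 8 with the largest rise and 8 with the largest fall among called protein-coding genes with a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries; up to 4 members with the smallest p in each called response list; and 17 genes fixed in advance. Any other gene is said to have been chosen after its values were seen. Alternatives were DESeq2 size factors (RLE), upper-quartile factors, no filter, a filter of 5 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, the fit of the compared libraries, replicate numbers as a block, and leaving out each library. A limma-voom fit with a spread for each group, a fit of the 9 libraries of a genotype, and the fit of the compared libraries for the lists and for the overlap of the responses were added after seeing the data. Upper-quartile and RLE factors moved fold changes by at most 0.05 on the log2 scale against TMM. Pairs of replicates differed beyond sampling noise in all 18 cases (chi-square per degree of freedom 3.3 to 142), as did the 135 pairs of libraries of different groups (9.44 to 214), so no library is a copy of another. All 18 samples were used, with total counts of 15532973 to 21128507 per library. Since replicates varied by more than counting alone gives, the depth alone did not set the precision.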

Results

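RNA from macrophages grown out of the bone marrow of wild-type and TLR4-knockout mice was sequenced after 24 h with water, GM or MDP. TLR4 is the receptor through which macrophages sense bacterial lipopolysaccharide, and GM and MDP are fragments of the bacterial cell wall. Each of the 6 groups held 3 libraries, 18 in all, with total counts of 15532973 to 21128507 per library. Mitochondrial genes took 2.96% to 3.79% of the counts. The first principal component of the 1000 most variable genes held 54.6% of the variance and separated the genotypes, and the second held 15%. Wild-type water replicate 3 lay apart on the second component, at 43.5 against 5.5 and 5.8 for replicates 1 and 2.

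**Figure D1:**
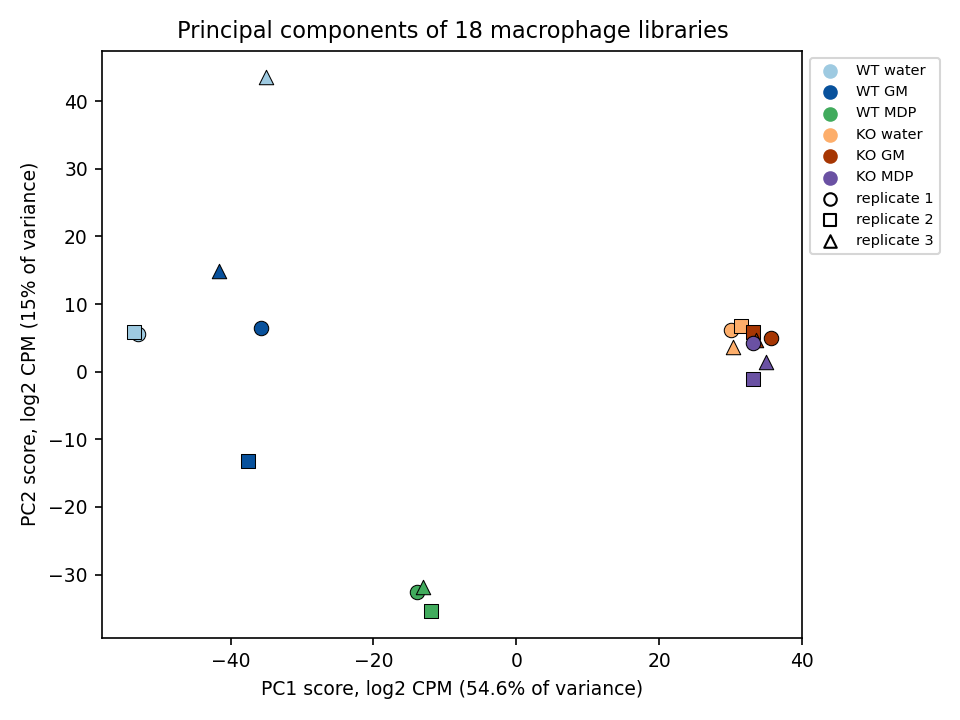
Scores of the 18 libraries on the first (54.6% of variance) and second (15%) principal components of log2 CPM, colour by group and symbol by replicate. The 9 knockout libraries lie at 30.1 to 35.6 on the first component, the wild-type MDP libraries at -13.9 to -11.9, and wild-type water replicate 3 stands apart at 43.5 on the second.

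Tlr4 itself (ENSMUSG00000039005, GRCm39 chromosome 4, 66745821 to 66848521) was measured first in every library. It ranged from 149 to 230 CPM in wild-type water, 179 to 192 in wild-type GM and 117 to 131 in wild-type MDP. In knockout cells it ranged from 46.3 to 52.9 CPM in water, 36.5 to 39.5 in GM and 48.2 to 49.2 in MDP, below every wild-type library. The knockout water mean, 50.4 ± 3.59 CPM (SD, n = 3), was 28.3% of the wild-type mean of 178 ± 44.9 (log2 fold change -1.82, SE 0.13, adjusted p = 5.9e-08). A long noncoding RNA inside the Tlr4 gene (ENSMUSG00000121059, 66762713 to 66764269), looked at after the values were seen, was lower in knockout water by more (log2 fold change -3.57, adjusted p = 1.3e-08). The labels do not say which part of Tlr4 the allele lacks, and counts over other parts of the gene would remain.

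The first question was what GM does to wild-type macrophages, GM being named a TLR4 agonist in the series title. Inflammatory cytokine genes were among those that rose most. Il6, a fever and acute-phase cytokine (ENSMUSG00000025746, chromosome 5, 30218112 to 30224979), went from 0.722 ± 0.198 CPM in water to 102 ± 41.7 CPM with GM (SD, n = 3), a 140-fold rise (log2 7.13, SE 0.35, adjusted p = 6.4e-09). Il1b, which encodes interleukin-1 beta (chromosome 2, 129206490 to 129213059), went from 8.28 ± 3.41 to 697 ± 268 CPM (log2 6.39, SE 0.33, adjusted p = 8.2e-09). Il12b, the shared subunit of interleukins 12 and 23 (chromosome 11, 44290890 to 44304860), rose from 3.19 ± 2.51 to 405 ± 162 CPM (log2 7, SE 0.51, adjusted p = 4.5e-07). Over the alternatives its log2 change ran from 6.48 to 7.62. Nos2, the inducible nitric oxide synthase (chromosome 11, 78811613 to 78851080), rose from 1.8 ± 1.27 to 131 ± 54.2 CPM (log2 6.18, SE 0.45, adjusted p = 4.3e-07). Every GM library lay above every water library for these genes, which chance alone gives in 10% of genes for 3 against 3 in either direction.

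Of 24 tested genes for inflammatory cytokines and chemokines, 16 rose with GM in wild type, 0 fell and 8 did not pass (17 rose when adjusted over the list alone), with a median log2 fold change of 2.28. Among them were Tnf (log2 2.23, SE 0.18) and the T cell attractant Ccl5 (log2 4.46, SE 0.18). Of 24 NF-kB targets and feedback regulators, genes that this inflammatory transcription factor switches on, 21 rose and 0 fell (23 adjusted over the list alone). Among them were Tnfaip3 (log2 1.44), Nfkbia (log2 1.34) and Nfkb2 (log2 1.12), which restrain or carry NF-kB signalling, and the co-stimulatory receptor Cd40 (log2 2.89). Of 38 type I interferon response genes, 30 rose and 0 fell (38 adjusted over the list alone), such as Isg15 (log2 3.4), Irf7 (log2 3.46) and Oasl1 (log2 3.78). Of 25 antimicrobial and immunometabolic effectors, 12 rose and 0 fell (17 rose and 1 fell adjusted over the list alone), including the acute-phase gene Saa3 (log2 3.48), the mycobacterial glycolipid receptor Clec4e (log2 3.93) and the arginine transporter Slc7a2 (log2 2.78). In the list of anti-inflammatory mediators 7 of 27 rose and 1 fell (8 and 3 adjusted over the list alone), with the adenosine receptor gene Adora2a at log2 2.07. The camera adjusted p of these 5 lists ran from 2.84e-77 to 0.000257, and all 5 held with an estimated correlation (adjusted p = 7.25e-08 to 0.012).

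Pattern recognition receptors (3 of 27 rose, 1 fell) and inflammasome genes (6 of 20 rose) were called as lists and held with an estimated correlation (adjusted p = 0.0144 and 0.011). The lipopolysaccharide co-receptor gene Cd14 rose by log2 2.38 (2.14 to 3.02 over the alternatives) and the inflammasome sensor gene Mefv by log2 1.6 (1.48 to 1.7). Adjusted over the list alone their counts were the same, 3 with 1 lower and 6. The inflammasome difference was small, with a mean list level (over libraries, each the median log2 level of the genes) higher by 0.18 with GM and by 0.12 without water replicate 3. GM replicate 3, at -0.29 on that list, lay below water replicates 1 and 2 (-0.18 and -0.23). The pattern recognition list lay at -0.04, -0.04 and -0.1 in water and at 0.15, 0.2 and -0.12 with GM, so GM replicate 3 lay below every water library. Antigen presentation (5 of 22 rose) and the cell cycle list (1 of 32 fell) were called with the preset correlation, but their adjusted p was 0.531 and 0.655 with an estimated correlation. The cell cycle list lay at -1.53 and -1.91 in GM replicates 1 and 3 and at -1.78 in water replicate 3 (median log2 level relative to the mean of all libraries). GM replicate 2 lay at -0.36 and water replicates 1 and 2 at -0.1 and -0.23. Antigen presentation lay at 0.06, 0.07 and -0.86 in water replicates 1 to 3 and at 0.05, 0.66 and -0.06 with GM, so water replicate 3 set much of its rise. Lists for alternative activation, growth factors, glycolysis, oxidative phosphorylation, cholesterol biosynthesis, LXR targets, lysosome, NRF2 targets and unfolded protein response were not called for GM in wild type (camera adjusted p = 0.065 to 0.966). Among cell type markers, stromal genes (2 of 14 fell), monocyte genes (4 of 12 rose) and neutrophil genes (2 of 13 rose) were called with the preset correlation only. Their adjusted p was 0.288, 0.0927 and 0.253 with an estimated correlation, and the list levels of the water and GM libraries overlapped. Levels of Nod2, the cytosolic receptor for muramyl peptides, of its kinase Ripk2 and of Tlr4 did not pass (log2 0.56, 0.12 and 0.06).

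By the edgeR quasi-likelihood fit of all 18 libraries, 729 of 15450 genes differed between GM and water in wild type, 609 higher and 120 lower. By the fit of the 6 compared libraries 96 genes passed, all of them higher and all among the 729, with a median log2 change of 2.24. Il6, Il1b, Il12b, Nos2, Tnf, Ccl5, Tnfaip3, Nfkbia, Isg15, Irf7, Saa3 and Clec4e passed in both, while Cd14, Tlr2, Acod1, Cxcl10, Ifit1, Il10 and the genes named as lower, such as Myl9 (log2 -2.13) and Tfrc (log2 -0.69), passed in the first alone. That fit of 6 had 0 genes lower, with 974 at an unadjusted p under 0.05 in either direction, and DESeq2 on all 18 libraries called 1073 in either direction. Without water replicate 3 the edgeR count was 3349, with 1675 higher and 1674 lower, so the excess of higher genes did not hold without that library. Water replicate 3 lay with GM replicates 1 and 3 on the cell cycle list. The calls gained without it therefore cannot be told apart from whatever sets those libraries apart. In simulated data with the spread of each group, 81% of the calls of the fit of all 18 libraries and 10.6% of those of the fit of 6 were false for this comparison. These shares depend on how many changed genes were planted and do not give the share among the real calls.

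**Figure D2:**
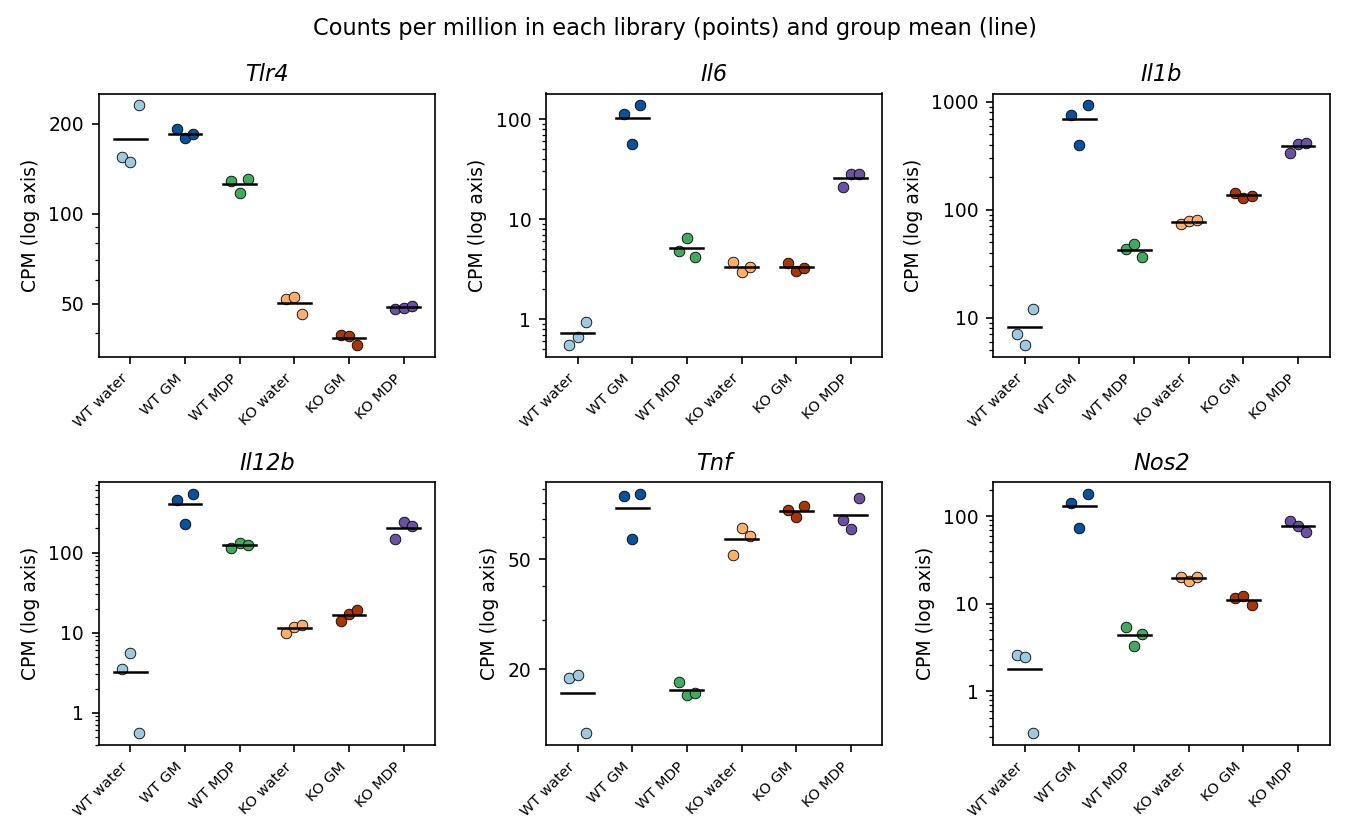
CPM (log axis) of 6 genes in each of the 18 libraries, points for libraries and lines for group means (n = 3). Il6 lies at 55.8 CPM or more in every wild-type GM library and at 3.3 ± 0.295 CPM in knockout GM, and Tlr4 lies lower in all knockout libraries.

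In knockout macrophages the comparison with water asks what GM does without intact TLR4. Il6 stayed at 3.3 ± 0.295 CPM with GM against 3.35 ± 0.367 in water (SD, n = 3; log2 -0.02, 95% interval -0.66 to 0.62, adjusted p = 1). Il1b was at 136 ± 7.66 against 77.4 ± 2.85 CPM (log2 0.81, 95% interval 0.26 to 1.36, adjusted p = 0.73 in the fit of all 18 libraries). It passed as higher in the fit of the 6 compared libraries (adjusted p = 1.1e-14) and with a spread for each group (adjusted p = 0.003). Nos2 was at 11.1 ± 1.33 against 19.5 ± 1.06 CPM (log2 -0.82, 95% interval -1.58 to -0.05, adjusted p = 0.97 in the fit of all 18 libraries). It passed as lower in the other 2 fits (adjusted p = 1.1e-06 and 0.046). The macrophage chemokine gene Ccl6 fell (4870 ± 211 to 3150 ± 231 CPM, log2 -0.63, SE 0.1, adjusted p = 0.047), as did the matricellular gene Ccn3 (71.1 ± 13.7 to 33.9 ± 1.12 CPM, log2 -1.07, SE 0.16, adjusted p = 0.039). Named after its values were seen, the noncoding RNA ENSMUSG00000121059 inside Tlr4 fell too (log2 -1.93, adjusted p = 0.0395).

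The knockout libraries varied little, and the fit of the 6 compared libraries called many small changes with GM. In that fit 19 of 22 NRF2 and oxidative stress genes rose, among them Prdx1, a peroxide-reducing enzyme (log2 0.67), and the glutathione conjugate exporter gene Abcc1 (log2 0.59), and 0 fell. In the same fit 13 of 24 NF-kB targets rose, such as Tnfaip3 (log2 0.27) and the mitochondrial superoxide dismutase gene Sod2 (log2 0.43), with 0 lower. Meanwhile 19 of 32 cell cycle genes fell, such as the proliferation marker Mki67 (log2 -0.35), with 0 higher. Interferon genes fell in 9 of 38 cases with 0 higher, and antimicrobial effectors rose in 12 of 25 and fell in 2, the scavenger receptor gene Marco by log2 1.45 upwards. Camera on the fit of all 18 libraries called the NF-kB list (median log2 0.2, adjusted p = 9.36e-08, and 0.00418 with an estimated correlation). Calls for NRF2 targets (median log2 0.42), interferon (median log2 -0.27), antimicrobial effectors (median log2 0.3) and cell cycle (median log2 -0.29) were lost with an estimated correlation (adjusted p = 0.324, 0.454, 0.172 and 0.615). Calls for growth factors, glycolysis, LXR targets, lysosome and unfolded protein response were lost as well (adjusted p = 0.273, 0.486, 0.172, 0.177 and 0.172). The correlation was estimated over all 18 libraries, the more variable wild-type ones included. Between knockout water and GM libraries the levels of the NRF2, antimicrobial and cell cycle lists did not overlap, while those of the interferon list did. Cytokines and chemokines were not called as a list (median log2 0.04, adjusted p = 0.561). In the fit of 6, 5 of the 24 rose, among them Il1b, Il12b (log2 0.58) and Tnf (log2 0.34), and 2 fell.

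By edgeR, 3 genes differed between GM and water in knockout with all 18 libraries, 0 higher and 3 lower, with 749 at an unadjusted p under 0.05 and 38 by DESeq2. Without any single library of the comparison the count was 0. In no fixed list did a member pass over all genes (0 of 24 cytokines, 0 of 24 NF-kB targets), and adjusted over the list alone 3 NF-kB targets rose and 0 cytokine genes did. The fit of the 6 compared libraries called 1211 genes, 586 higher and 625 lower, of which 26 and 34 changed at least 2-fold and whose median absolute log2 change was 0.3. The limma-voom fit with a spread for each group, added after seeing the data, called 569. The labels give no batch, so for these small changes a batch shared within a group and an effect of GM cannot be told apart.

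In wild-type macrophages MDP, a muramyl peptide, was compared with water. Interferon genes were higher and stromal ones lower, although both list calls were lost with an estimated correlation (adjusted p = 0.059 and 0.121). Il12b rose from 3.19 ± 2.51 to 123 ± 9.65 CPM (SD, n = 3; log2 5.28, SE 0.48, adjusted p = 2.3e-06). Il6 rose from 0.722 ± 0.198 to 5.14 ± 1.23 CPM (log2 2.83, SE 0.36, adjusted p = 5e-05) and Il1b from 8.28 ± 3.41 to 42.6 ± 5.69 CPM (log2 2.36, SE 0.28, adjusted p = 2.8e-05). Mmp9, a secreted gelatinase, rose from 7.06 ± 3.97 to 115 ± 23 CPM (log2 4.02, SE 0.28, adjusted p = 1.5e-07), and Retnla, a marker of alternative activation, by log2 7.06 (SE 0.78) from 0.0609 ± 0.105 CPM. Tnf was at 16.9 ± 1 against 16.4 ± 4.11 CPM and did not pass (log2 0.04, adjusted p = 0.89). Cyp26b1, which breaks down retinoic acid, fell from 22.4 ± 19.9 to 0.0703 ± 0.0793 CPM (log2 -8.1, SE 1.03), and the stromal chemokine Cxcl12 from 27.9 ± 20.4 to 0.641 ± 0.233 CPM (log2 -5.45, SE 0.75).

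Interferon response genes rose with MDP in wild type in 35 of 38 cases with 0 lower (36 adjusted over the list alone), including Irf7 (log2 3.42), Usp18 (log2 2) and Oasl1 (log2 2.86). The list's median log2 change was 1.83 and its camera adjusted p 3.42e-39, against an adjusted p = 0.059 with an estimated correlation. NF-kB targets rose in 16 of 24 cases with 0 lower (17 and 1 adjusted over the list alone; median log2 0.61), and their call held (adjusted p = 0.000259 with an estimated correlation). Cytokines and chemokines rose in 6 of 24 cases and fell in 1 (the same counts adjusted over the list alone), with a median of 0.03 and an adjusted p = 0.0744 with an estimated correlation. Cholesterol biosynthesis genes rose in 14 of 24 cases (16 adjusted over the list alone), such as Pmvk (log2 1.73) and Fdft1 (log2 0.91). Oxidative phosphorylation genes fell in 15 of 29 (18 adjusted over the list alone), and growth factor and repair genes fell in 9 of 24 (10 adjusted over the list alone), such as the urokinase receptor gene Plaur (log2 -1.35), with 1 higher. These 3 calls were lost with an estimated correlation (adjusted p = 0.274, 0.394 and 0.274), as was that of antimicrobial effectors (9 of 25 higher, adjusted p = 0.274). The mean level of the cholesterol list differed by 0.7, and by 0.43 without water replicate 3.

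Markers of other cell types moved with MDP. All 14 tested fibroblast and stroma genes fell with MDP in wild type (14 adjusted over the list alone, median log2 -3.19), with an adjusted p = 0.121 with an estimated correlation. Among them, named after their values were seen, were the collagen gene Col1a1 (log2 -3.01) and the collagen-binding proteoglycan gene Dcn (log2 -3.23). The stromal level differed between the water libraries too, at 3.82, 3.77 and 1.23 in replicates 1, 2 and 3 (median log2 relative to the mean of all libraries). Neutrophil markers rose in 6 of 13 cases (adjusted p = 0.165 with an estimated correlation). Macrophage identity genes rose in 6 of 21 cases and fell in 1 (median log2 0.18, adjusted p = 0.509 with an estimated correlation). The osteoclast list was called upwards on a mean of log2 0.22 although its median was log2 -0.33 (2 of 8 rose and 2 fell), with an adjusted p = 0.121 with an estimated correlation. Without water replicate 3 the mean list level differed by 0.01 instead of 0.17 for macrophage identity and by -0.02 instead of 0.19 for the osteoclast list.

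By edgeR, 3810 genes differed between MDP and water in wild type, 1725 higher and 2085 lower, and 1271 by the fit of the 6 compared libraries, 716 higher and 555 lower. Both fits called 1257 genes, 703 higher and 554 lower, Il12b, Il6, Il1b, Mmp9, Retnla, Irf7, Cyp26b1 and Cxcl12 among them. By limma-voom with a spread for each group Il6 (adjusted p = 0.3) and Retnla (adjusted p = 0.057) did not pass. The others named here did.

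MDP against water in knockout macrophages addresses how far the MDP response needs TLR4, and inflammatory genes rose. Il12b rose from 11.3 ± 1.32 to 201 ± 46.8 CPM (SD, n = 3; log2 4.15, SE 0.44, adjusted p = 0.00011) and Il6 from 3.35 ± 0.367 to 25.9 ± 4.11 CPM (log2 2.95, SE 0.28, adjusted p = 4.7e-05). Il1b rose from 77.4 ± 2.85 to 387 ± 46.5 CPM (log2 2.32, SE 0.27, adjusted p = 2e-04) and Nos2 from 19.5 ± 1.06 to 76.8 ± 10.6 CPM (log2 1.98, SE 0.35, adjusted p = 0.006). Arg1, the arginase of alternative activation, rose from 2.93 ± 0.841 to 32.7 ± 13.7 CPM (log2 3.48, SE 0.43) and Cd40 from 5.25 ± 1.04 to 30.2 ± 5.03 CPM (log2 2.52, SE 0.18). The mannose receptor gene Mrc1 fell from 418 ± 12 to 214 ± 19.2 CPM (log2 -0.97, SE 0.16) and urokinase, Plau, from 121 ± 4.68 to 60.1 ± 5.92 CPM (log2 -1.01, SE 0.1).

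Of the 24 cytokines and chemokines 9 rose with MDP in knockout and 0 fell (10 adjusted over the list alone, median log2 1.15), and of the 24 NF-kB targets 9 rose and 0 fell (15 adjusted over the list alone, median log2 0.38). Antimicrobial effectors rose in 5 of 25 cases (13 adjusted over the list alone, median log2 0.83), such as Saa3 (log2 1.48) and Slc7a2 (log2 1.47). These 3 lists were called by camera (adjusted p = 6.07e-27, 8.8e-24 and 5.38e-16) and held with an estimated correlation (adjusted p = 9.99e-06, 9.99e-06 and 0.00462). The anti-inflammatory list held too (adjusted p = 0.0205 with an estimated correlation), with 5 of 27 higher and 1 lower (9 and 2 adjusted over the list alone), Socs3, a brake on cytokine signalling, rising by log2 0.91. Its median log2 level lay at -0.5, -0.18 and -0.06 in knockout water replicates 1 to 3 and at -0.06, 0.02 and -0.06 with MDP. Water replicate 1 thus set much of the rise of this list. Interferon genes rose in 5 of 38 cases (11 adjusted over the list alone, median log2 0.63), with an adjusted p = 0.206 with an estimated correlation. The cell cycle list fell in 1 of 32 genes (median log2 -0.64, adjusted p = 0.425 with an estimated correlation). Glycolysis and HIF-1 targets rose in 3 of 24 and fell in 1 (adjusted p = 0.206 with an estimated correlation).

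By edgeR, 427 genes differed between MDP and water in knockout, 246 higher and 181 lower, all of them among the 2956 of the fit of the 6 compared libraries (1435 higher and 1521 lower). DESeq2 called 749, and with 1 library left out the edgeR count fell to 185 to 310. In the fit of 6, 37 of the 38 interferon genes, 15 of the 24 cytokines and 20 of the 24 NF-kB targets were higher, each with 0 lower.

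**Figure D3:**
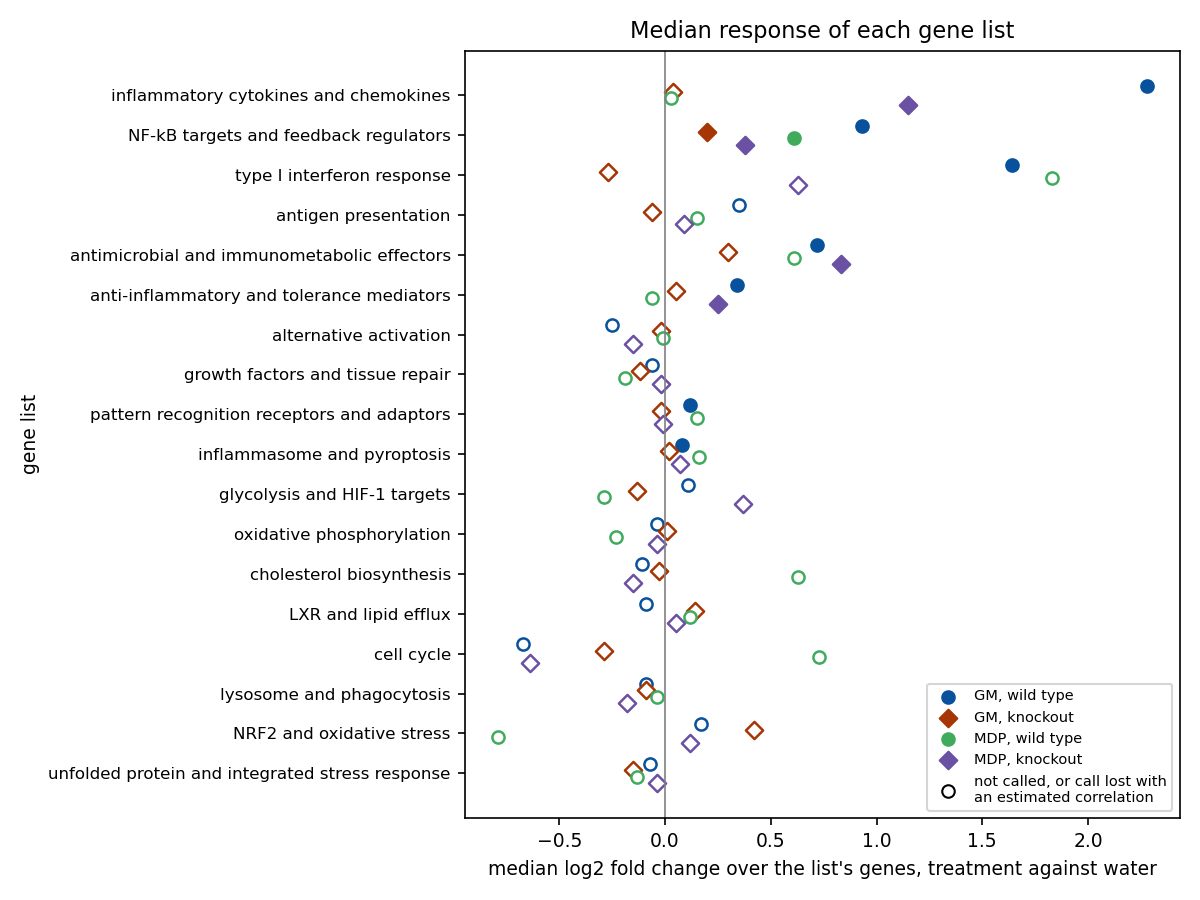
Median log2 fold change of the tested genes of 18 response lists against water, circles for wild type and diamonds for knockout. Filled symbols are camera calls that held with an estimated correlation; cytokines and chemokines lie at 2.28 with GM and 0.03 with MDP in wild type, and at 0.04 and 1.15 in knockout.

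GM and MDP are structurally related, the labels giving GM as a disaccharide without the peptide and MDP as N-acetylmuramic acid with 2 amino acids and without the glucosamine. They were compared at the same time point, with doses that are not stated. In wild type, Il6 was higher with GM than with MDP by log2 4.3 (102 ± 41.7 against 5.14 ± 1.23 CPM, SD, n = 3; SE 0.29, adjusted p = 2.9e-07). Il1b was higher by log2 4.03 (SE 0.29), Nos2 by log2 4.9 (SE 0.41), Tnf by log2 2.19 (SE 0.18) and Ptgs2, the inducible cyclooxygenase, by log2 4.97 (SE 0.54). Socs3 was at 108 ± 14.4 CPM with GM and 11.2 ± 0.424 with MDP (log2 3.26, SE 0.11, adjusted p = 5.6e-11). Retnla (log2 -4.46, SE 0.61), the endothelial lipase gene Lipg (log2 -3.47, SE 0.45) and Mmp9 (log2 -2.85, SE 0.27) were lower with GM. Ifit1 and Nod2 did not pass, with 95% intervals of the log2 difference of -0.21 to 1.58 and -0.04 to 0.85, although Ifit1 passed in the fit of the 6 compared libraries.

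Cytokines and chemokines were higher with GM than with MDP in wild type in 16 of 24 cases and lower in 0 (19 adjusted over the list alone, median log2 1.47, camera adjusted p = 1.03e-24, and 3.24e-05 with an estimated correlation). NF-kB targets were higher in 10 of 24 and lower in 2 (12 and 3 adjusted over the list alone), antimicrobial effectors in 12 and 2 of 25 (14 and 2) and anti-inflammatory mediators in 6 and 2 of 27 (6 and 2). These calls held (adjusted p = 0.0247, 0.0288 and 0.0166 with an estimated correlation). Interferon genes were higher in 6 of 38 and lower in 2, and the list was not called (median log2 -0.15, mean 0.05, adjusted p = 0.715). The cell cycle list was lower with GM in 27 of 32 genes (30 adjusted over the list alone, median log2 -1.46), such as the mitotic checkpoint gene Bub1 (log2 -1.81), and cholesterol biosynthesis in 15 of 24 (21 adjusted over the list alone). NRF2 targets were higher in 8 of 22 with 1 lower (14 and 1 adjusted over the list alone) and stromal markers higher in 10 of 14 (11 adjusted over the list alone). With an estimated correlation these 4 calls were lost (adjusted p = 0.291, 0.172, 0.389 and 0.199). NRF2 targets stood at 1.01 and 1.05 in GM replicates 1 and 3 and at -0.14 in replicate 2. By edgeR 3001 genes differed, 1553 higher with GM and 1448 lower, and 1488 by the fit of the 6 compared libraries (767 and 721), with 1431 in both. With 1 library left out the edgeR count ran from 1774 to 3799.

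In knockout the order was the opposite. Il12b was lower with GM than with MDP by log2 -3.57 (16.9 ± 2.85 against 201 ± 46.8 CPM, SD, n = 3; SE 0.42, adjusted p = 0.00046). Il6 was lower by log2 -2.97 (SE 0.28), Nos2 by log2 -2.79 (SE 0.37), Arg1 by log2 -3.44 (SE 0.43) and Cd40 by log2 -2.23 (SE 0.17). Slc40a1, the iron exporter, was higher with GM by log2 1.73 (SE 0.33, adjusted p = 0.016). Tnf did not pass (log2 0.04, 95% interval -0.31 to 0.4), nor did Ripk2 (95% interval -0.53 to 0.08). Cytokines and chemokines were lower with GM in 8 of 24 cases and higher in 0 (12 lower adjusted over the list alone, median log2 -1.35, camera adjusted p = 6.42e-31, and 6.95e-06 with an estimated correlation). Interferon genes were lower in 7 of 38 (32 adjusted over the list alone) and glycolysis and HIF-1 targets in 4 of 24 (16 lower and 1 higher adjusted over the list alone), with an adjusted p = 0.0399 for both with an estimated correlation. By edgeR 242 genes differed, 67 higher and 175 lower with GM, and 2516 by the fit of the 6 compared libraries, with 240 in both. DESeq2 called 486, and with any 1 library of the comparison left out the edgeR count fell to 94 to 146.

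Without treatment, knockout cultures differed from wild-type ones in many genes, which gives the baseline of the responses. The stromal list differed as well, at 3.82, 3.77 and 1.23 in wild-type water and -0.59, -1.29 and -1.3 in knockout water (median log2 level). Part of the difference may thus lie in the mix of cells, which was not tested. Il1b stood at 77.4 ± 2.85 CPM in knockout and 8.28 ± 3.41 in wild type (SD, n = 3; 9.33-fold, log2 3.22, SE 0.29, adjusted p = 1.3e-06) and Tnf at 59.2 ± 6.88 and 16.4 ± 4.11 CPM (log2 1.85, SE 0.18, adjusted p = 1.6e-06). Tlr2, the receptor for bacterial lipoproteins, stood at 450 ± 19.5 and 100 ± 17.8 CPM (log2 2.16, SE 0.14, adjusted p = 2.3e-08) and the iron-binding neutrophil protein gene Lcn2 at 106 ± 16.4 and 2.9 ± 2.57 CPM (log2 5.19, SE 0.43). The fractalkine receptor gene Cx3cr1 (log2 5.41, SE 0.59) and the fatty acid receptor gene Gpr84 (log2 4.61, SE 0.15) were higher in knockout. The matricellular gene Ccn2 (log2 -7.49, SE 0.51), Cxcl12 (log2 -8.49, SE 0.98), the growth factor gene Hbegf (log2 -3.52, SE 0.2) and Plau (log2 -2.32, SE 0.1) were lower.

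NF-kB targets were higher in knockout water in 12 of 24 cases and lower in 1 (13 and 1 adjusted over the list alone), and antimicrobial effectors in 14 of 25 with 0 lower (14 and 1). Inflammasome genes were higher in 11 of 20 and lower in 1 (11 and 2 adjusted over the list alone), and growth factor and repair genes lower in 11 of 24 and higher in 3 (the same adjusted over the list alone). Monocyte markers were higher in 6 of 12 with 2 lower and neutrophil markers higher in 10 of 13, such as the antimicrobial peptide gene Camp (log2 3.52), named after its value was seen. These 6 calls held with an estimated correlation (adjusted p = 0.00166, 0.0178, 0.0266, 0.0178, 0.0249 and 0.0464). Fibroblast and stroma markers were lower in 13 of 14 (13 adjusted over the list alone, median log2 -4.71), with an adjusted p = 0.0882 with an estimated correlation. The lists for cell cycle (25 of 32 higher, 1 lower), cholesterol biosynthesis (17 of 24 higher) and interferon response (25 of 38 higher) were called with the preset correlation only (adjusted p = 0.314, 0.2 and 0.32 with an estimated correlation). Without wild-type water replicate 3 the mean list level differed by 0.53 instead of 0.8 for cholesterol biosynthesis and by 0.56 instead of 0.96 for interferon response. The same held for LXR targets (9 of 21 higher, 2 lower), NRF2 targets (11 of 22 lower, 1 higher) and alternative activation (9 of 20 lower, 2 higher), with an adjusted p = 0.198, 0.632 and 0.198 with an estimated correlation. The NRF2 list lay at -0.23, -0.12 and 1.34 in wild-type water replicates 1 to 3 against -0.39 to -0.34 in knockout water, so replicate 3 set most of its difference. Calls were also lost for dendritic cell (7 of 11 lower), lymphocyte (5 of 11 higher, 2 lower) and mast cell (5 of 8 higher) markers (adjusted p = 0.442, 0.105 and 0.216 with an estimated correlation). The dendritic cell list lay at 0.68, 0.58 and -1.39 in wild-type water against -1 to -0.85 in knockout water, with replicate 3 below knockout. Osteoclast (2 higher and 2 lower of 8, adjusted p = 0.604) and megakaryocyte markers (1 of 5 lower, adjusted p = 0.978) were not called.

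By edgeR 5110 genes differed between the genotypes in water, 2250 higher and 2860 lower in knockout, and 2258 by the fit of the 6 compared libraries, 976 higher and 1282 lower, with 2242 in both. With replicate numbers as a block 855 genes passed, 359 higher and 496 lower. Within 20 Mb of Tlr4, where a knockout strain made in another background would keep donor sequence, 43 of 110 tested genes were called (39.1%) against 33% of the other 15339 (odds ratio 1.3, Fisher's exact test, 2-sided p = 0.19).

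The test of the difference between genotypes asks which GM responses were larger in wild type. Larger and smaller refer to the signed log2 change, so a gene that fell more in wild type counts as smaller. For Il6 the GM response was larger in wild type by log2 7.15 (SE 0.46, adjusted p = 3e-07; 0.722 to 102 CPM in wild type, 3.35 to 3.3 CPM in knockout, n = 3 per group). The difference was log2 7 for Nos2 (SE 0.57), 6.42 for Il12b (SE 0.63), 5.58 for Il1b (SE 0.39), 4.2 for Ccl5 (SE 0.23), 3.41 for Saa3 (SE 0.24) and 1.89 for Tnf (SE 0.24, adjusted p = 0.00024). By limma-voom with a spread for each group that for Il12b did not pass (adjusted p = 0.071). With GM, Tnf stood at 76.8 ± 15.1 CPM in wild type and 74.7 ± 3.59 in knockout, so its difference lay in the water levels (16.4 and 59.2 CPM). Saa3 went from 59 to 659 CPM in wild type and from 325 to 341 CPM in knockout. The response was larger in wild type for 12 of 24 cytokines (16 adjusted over the list alone), 14 of 24 NF-kB targets (21), 24 of 38 interferon genes (36) and 7 of 25 antimicrobial effectors (10, and 1 smaller). It was smaller for 0 of them over all genes. Their camera adjusted p was 1.61e-69, 1.09e-39, 1.85e-92 and 1.3e-24, and 1.93e-07, 7.33e-07, 0.00117 and 0.00103 with an estimated correlation. With GM the antimicrobial list lay at 0.25, -0.09 and 0.56 in wild type and at 0.36, 0.32 and 0.26 in knockout. In water it lay at -1.15, -1.09 and -1.07 and at 0.08, 0.08 and 0.07, so its difference lay in the water levels. The NF-kB list lay at -0.62, -0.59 and -0.85 in wild-type water and -0.14, -0.09 and -0.06 in knockout water. With GM it lay at 0.3, 0.39 and 0.3 against 0.1, 0.1 and 0.01, so part of its difference lay in water too. For the transferrin receptor gene Tfrc the signed difference was negative (log2 -1.05, SE 0.16, adjusted p = 0.0015). Tfrc went from 166 to 103 CPM with GM in wild type and from 218 to 280 CPM in knockout.

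By edgeR 287 genes differed in their GM response between the genotypes, 273 larger and 14 smaller in wild type, and 145 by the fit of the 12 compared libraries (143 and 2), with 144 in both. Without wild-type water replicate 3 the edgeR count was 1110, with 706 larger and 404 smaller in wild type, and DESeq2 called 443. The 609 genes raised by GM in wild type had a median log2 change of 1.08 there and 0.06 in knockout, where edgeR called 0 of them higher with all 18 libraries and 100 higher and 33 lower with the 6 knockout libraries. Of all 15450 genes 749 were at an unadjusted p under 0.05 in knockout, and DESeq2 called 38. Of the 96 genes raised in both fits (median log2 2.24 in wild type and 0.12 in knockout), 89 had a larger response in wild type. In knockout 26 of them were called higher with GM by the fit of the 6 libraries, and 69 with MDP by that of all 18. Across genes, which are not independent replicates, the responses to GM in the genotypes correlated with Pearson's r 0.13 (0.21 with the stricter filter) and Spearman's rho 0.12.

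For MDP the difference between genotypes ran in both directions. The MDP response was larger in wild type for the interferon gene Irf7 (log2 2.45, SE 0.38, adjusted p = 0.0012), for Mmp9 (log2 3.11, SE 0.37, adjusted p = 0.00013) and for the non-canonical NF-kB subunit gene Relb (log2 1.63, SE 0.29, adjusted p = 0.0026). The signed difference was negative for Socs3 (log2 -3.56, SE 0.15, adjusted p = 1.1e-09). It was negative too for the related brake Socs1 (log2 -2.25, SE 0.21, adjusted p = 1.4e-05). So it was for the basement membrane collagen gene Col4a1 (log2 -4.94, SE 0.53) and Ripk2 (log2 -1.11, SE 0.2, adjusted p = 0.0033). The mean level of each of these genes fell with MDP in wild type and rose in knockout. Socs3 went from 70.3 to 11.2 CPM in wild type and from 74.9 to 141 CPM in knockout. Socs1 went from 35.3 to 12.9 and from 10.2 to 17.8 CPM, and Ripk2 from 40.8 to 23 and from 22.1 to 26.9 CPM. The rise of Ripk2 in knockout did not pass in the fit of all 18 libraries. For Il6 the difference was log2 -0.12 (95% interval -1.22 to 0.99), for Il1b log2 0.04 and for Il12b log2 1.13 (SE 0.6, adjusted p = 0.27), none of which passed. Interferon genes had a larger response in wild type in 16 of 38 cases with 0 smaller (27 adjusted over the list alone, median log2 1.16). So did cholesterol biosynthesis genes in 7 of 24 (14 adjusted over the list alone), cell cycle in 4 of 32 (28 adjusted over the list alone) and NF-kB targets in 5 of 24 with 1 smaller (9 and 3 adjusted over the list alone). The stromal list lay at 3.82, 3.77 and 1.23 in wild-type water and at -0.32, -0.42 and 0.14 with MDP. In knockout it lay at -0.59, -1.29 and -1.3 in water and at -0.98, -1.32 and -1.87 with MDP. With the deeper fall in wild type, the signed difference was negative for 6 of 14 stromal genes (12 adjusted over the list alone). Each of these calls was lost with an estimated correlation (adjusted p = 0.219, 0.219, 0.486, 0.219 and 0.144). Without wild-type water replicate 3 the difference in mean list level fell from 0.81 to 0.54 for cholesterol biosynthesis and from 1.58 to 1.04 for the cell cycle.

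By edgeR 1222 genes differed in their MDP response between the genotypes, 618 larger and 604 smaller in wild type, and 1232 by the fit of the 12 compared libraries (716 and 516), with 1029 in both. DESeq2 called 1969, and with 1 library left out the edgeR count ran from 776 to 1857. The 1725 genes raised by MDP in wild type had a median log2 change of 0.95 there and 0.15 in knockout, where 156 were called higher and 23 lower with all 18 libraries and 560 higher and 131 lower with the 6 knockout libraries. In wild type 519 genes were called for both GM and MDP in 1 direction (455 higher and 64 lower) and 24 in opposite ones, against 84.2 if the calls were independent, and 75 by the fits of the compared libraries. Both responses share the same 3 water libraries, so chance alone links them. In 100 simulated draws the covariance of the fold changes had a median of 0.109 and a highest value of 0.424, against 0.208 observed, which 20 draws reached. The correlation had a median of 0.71 against 0.47 observed, which 67 draws reached. The shared calls by limma had a median of 0 and a highest value of 2776 against 207 observed, which 6 draws reached. The overlap was therefore not shown to exceed what shared controls give.

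**Figure D4:**
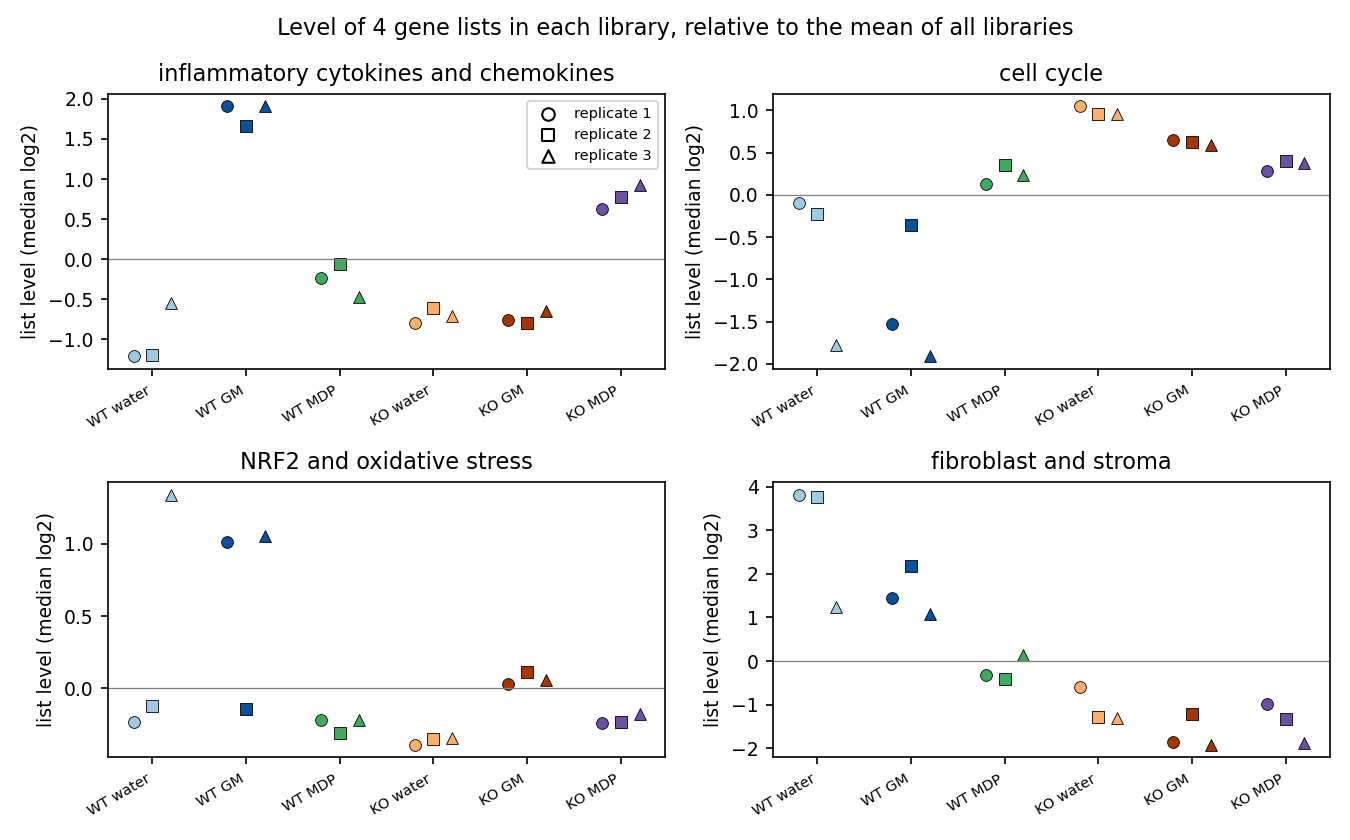
Median log2 level of 4 gene lists in each of the 18 libraries, relative to the mean of all libraries, symbols by replicate. Cytokines lie at 1.66 to 1.91 in the wild-type GM libraries, whereas cell cycle and NRF2 levels group wild-type water replicate 3 (-1.78 and 1.34) with GM replicates 1 (-1.53 and 1.01) and 3 (-1.91 and 1.05).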

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

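The tests valued 0.06, 0.12, -1.48, 273, 0.18 and 8.09 were chosen only after the result was seen, and those valued 16.4, -0.69 and 7.09 and the splits of the samples before.

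The response to GM differed between the genotypes in 287 genes by a test of the difference, and the 96 genes that both fits called higher with GM in wild type had a median log2 change of 2.24 there and 0.12 in knockout. For these 96 genes a pooled spread that hid changes as large as in wild type is argued against by that 0.12 (quartiles -0.1 and 0.31), and levels already high in knockout by a median log2 ratio of knockout water to wild-type GM of -1.48 (quartiles -2.5 and -0.84, 87.5% of genes lower). Over the 609 genes called by the fit of all 18 libraries the same values were 0.06 and -0.69. In simulation 81% of such calls were false, a share that depends on the few changed genes planted and is not that of the real calls. An unknown part of the 609 may be falsely called, and such genes would give a knockout median near 0 under any cause. For the rest of the 609 both explanations therefore stay open. How far the pooled spread hid smaller changes in these genes stays open as well. The fit of the 6 knockout libraries called 16.4% of the 609 genes higher, between the bounds set beforehand, and 27.1% of the 96. Over all 15450 genes that fit called 586 higher, where the fit of all 18 libraries called 0. It thus called smaller changes in knockout that the pooled spread left uncalled. For these, a culture or library batch shared within a group and an effect of GM cannot be told apart. GM acting through TLR4 and a TLR4-active contaminant of the GM preparation, such as lipopolysaccharide, cannot be told apart. Either gives the 273 genes with a larger response in wild type. No sample holds GM cleared of such a contaminant, or the contaminant alone. By the fit of the 12 compared libraries 145 genes differed, and 7 of 50 splits gave as many, the highest 2341, so chance was not excluded for the count, and a split with several times the real count points to a structure of the samples.

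The response to MDP differed between the genotypes in 1222 genes by a test of the difference. The wild-type MDP libraries lay 44% of the way from wild-type water to knockout water on the first principal component. Knockout cells in these libraries are argued against by the 35 genes at least 8-fold higher in knockout. Those genes lay 7.09% of the way from wild-type water to knockout MDP (median), whereas the 119 genes at least 8-fold lower lay at 92.4%. Fewer stromal cells do not account for the genes that rose 2-fold or more, since macrophage identity genes moved by a median log2 of 0.18, although a loss of stromal cells may explain genes that fell (Col1a2, the most abundant of the 14 listed stromal genes, at 47.7 CPM in water and 5.39 CPM with MDP; Thy1, Col5a1 and Acta2 of the 14 also stood at 8.18 CPM or more in knockout water). A culture or library batch of their own and an effect of MDP cannot be told apart, since all 3 MDP libraries were alike (variation 8.09%) and the labels give no batch. By the fit of the 12 compared libraries 1232 genes differed, against 1161 in the highest of the other splits. Only 1 of 50 splits, the real one, gave as many, which met the bound set beforehand. Since another split came near the real count, which points to a structure of the samples, the splits do not exclude chance for that count.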

How the results depend on the processing

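The limma-voom fit with a spread for each group, the fit of the 9 libraries of a genotype and the fit of the compared libraries for the overlap were tests chosen only after the result was seen.

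Of 10005 values for 591 named-gene results, 9035 stayed on the same side of the threshold, 665 fell below it, 305 passed it and 0 reversed. For 243 list results these were 2708, 200, 88 and 1 of 2997 values. The list that reversed was the cell cycle list for the GM response in wild type minus knockout, with an adjusted p of 0.945 without WT_GM replicate 3, and 5.11e-08 to 0.973 over the libraries left out.

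In wild type, fits that gave each group or comparison its own spread called fewer genes. For GM against water 173 passed by limma-voom with a spread for each group, 96 by the fit of the groups compared and 259 by the fit of 9 libraries, for MDP against water 1752, 1271 and 1540, and for GM against MDP 1488 and 728 by the latter pair. In knockout they called more: 569, 1211 and 1086 for GM against water, 2462, 2956 and 3031 for MDP against water, and 2009, 2516 and 2602 for GM against MDP. The genotypes in water differed in 2730 and 2258 genes by the first 2 of these fits, and the GM response in 127 and 145. In simulated data with each group's own spread the first 2 fits made 145 and 66 calls for GM in wild type (41.4% and 10.6% false) against 816 (81% false) by the fit of all 18 libraries. They made 199 and 203 against 124 for GM in knockout, and 204 and 203 against 130 for MDP in knockout. For these 3 comparisons unequal spread is thus enough to move the counts the same way, and for the others the cause was not tested. With replicate numbers as a block the genotypes differed in 855 genes, and the cause was not tested.

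DESeq2 called 38, 749 and 486 genes in knockout for GM, MDP and GM against MDP, and 443 and 1969 for the GM and MDP differences between genotypes. For GM in knockout, upper-quartile factors (2 higher, 4 lower) and no filter gave 6 each and the stricter filter 8. The list tests called fell from 122 to 37 with an estimated correlation, the genes shared by GM and MDP from 519 to 75 by the fits of the groups compared, and the correlations of the GM and MDP responses rose from 0.13 to 0.21 and from 0.19 to 0.3 with the stricter filter. For these changes the cause was not tested. Settings not named here left the counts within 1.5-fold. The odds ratio near Tlr4 was 1.11 and 1.39 with windows of 40 and 10 Mb. The share of genes higher with GM in wild type was 83.5% by edgeR, 68.5% by DESeq2, 50% without WT_water replicate 3, 100% by the fit of the groups compared and 99.4% by limma-voom with a spread for each group.

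With 1 library left out, counts ran from 508 to 3349 for GM in wild type, 2633 to 3981 for MDP, 1774 to 3799 for GM against MDP, 0 to 0 for GM in knockout (edgeR, 3 with all libraries), 185 to 310 for MDP, 94 to 146 for GM against MDP, 3824 to 5206 between genotypes, 197 to 1110 and 776 to 1857 for the GM and MDP differences, and 116 to 125 for lists. Without WT_water replicate 3 the counts were 3349 for GM in wild type, 1110 for the GM difference (706 larger and 404 smaller in wild type, against 273 and 14) and 1857 for the MDP difference. GM against MDP in wild type gave 1774 without WT_GM replicate 1, 1833 without WT_MDP replicate 2 and 1823 without WT_MDP replicate 3. MDP in knockout gave 185, 234 and 254 without KO_water replicates 1, 2 and 3, and 187 and 239 without KO_MDP replicates 2 and 3. GM against MDP in knockout gave 129, 96 and 95 without KO_GM replicates 1, 2 and 3, and 146, 94 and 125 without KO_MDP replicates 1, 2 and 3. The MDP difference gave 813 without WT_MDP replicate 3, 792 and 804 without KO_water replicates 1 and 2, and 801 and 776 without KO_MDP replicates 1 and 3. For each of these the cause was not tested, beyond the loss of 1 library.

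Replicate numbers did not pair the samples: libraries of 1 number correlated at -0.19 to 0.48 across groups after removal of group means, above 0.1 in 3 of 18 pairs, and 8 of 18 libraries correlated best with their own number. Depth was 15532973 to 21128507 counts per library. At this depth and with 1 spread for all groups, 38.8% of 1.5-fold and 98.5% of 4-fold changes were recovered in simulation for GM in wild type. No simulation varied the depth, so what it limits was not tested.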

Other observations

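The tests valued -0.54, 20.6, 2268 and 11.2 and the reading of the cytokine list for a swap partner were chosen only after the result was seen, and the tests valued 107 and -0.46 and the splits before.

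Wild-type water replicate 3 lay apart from replicates 1 and 2: of 10236 genes at 5 CPM or more, 422 were at least 2-fold higher in it than in both others and 899 lower, against 26 genes 2-fold apart between replicates 1 and 2. A lower depth (a total of 20.6 M counts, the highest of the 3), and fewer stromal cells as a source of the genes higher in it (macrophage identity genes at log2 -0.46, stroma at -1.99), are argued against. For a swap with a GM library the measure chosen beforehand came out as such a swap predicts, at 107% of the way to GM over 1675 genes, but those genes were chosen against replicates 1 and 2 and hold whatever replicate 3 shares with the GM libraries; over the 202 genes raised 4-fold or more, looked at afterwards, it was 11.2%. A swap is excluded for lack of a partner (lowest GM library at 1.66 on the cytokine list, replicates 1 and 2 at most -1.19), and a GM culture labelled as water by its own cytokine level of -0.54 and Il6 at 0.941 CPM against 55.8 or more. A culture or handling difference shared with GM replicates 1 and 3 stays open. The split that sets these 3 libraries against the other 3 called 2268 genes against 96 for the real split, but it was picked after their grouping had been seen and restates it. No biological explanation was tested, and the labels give no such batch.

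Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. Of the splits of wild-type water and GM, 2 gave at least the 96 genes of the real one, the highest 2268, which points to a structure of the samples. In each other comparison 1 split, the real one, gave as many. The real count and the highest other were 1271 and 0 for MDP against water in wild type, 1488 and 0 for GM against MDP in wild type, and 1211 and 1 for GM against water in knockout. They were 2956 and 0 for MDP against water in knockout, 2516 and 0 for GM against MDP in knockout, and 2258 and 0 for the genotypes in water.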
